A study of Mus musculus with 6 samples.

How the data were processed

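Gene expression was measured with Visium CytAssist, an assay that hybridizes probe pairs to the RNA of a tissue section and captures the ligated probes on a slide of barcoded spots, each of which can cover several cells. The 6 sections came from 6 B16-F10 melanomas, 1 per Rag1-deficient mouse, 3 in each group. CAL-101 is idelalisib, an inhibitor of PI3 kinase delta; it was applied to the T cells in culture, not to the mice. The sample descriptions call the tissue fresh frozen, while the protocol describes blocks of fixed, paraffin-embedded tissue, and nothing in the files settles which holds. Groups and replicate numbers were taken from the sample titles.

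The authors deposited raw UMI counts per gene and spot, made with Space Ranger 2.0.0 per the file headers and mapped to mm10 per the submitters' processing notes. They also deposited a table with the treatment group and an unsupervised cluster number for each spot; Seurat is named in the submitters' processing notes and its settings are not given. The clusters carry no names, so each is described here by the genes that lead it over the rest of the same tumors. In control 2, 1030 spots have no treatment group in that table; they carry a cluster number and were kept, and the comparison was repeated without them. Image scale factors were not used, and spot positions were not analysed here. A fixed list of 9 mitochondrially encoded genes has no measured member and was left out, which leaves 40 lists.

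The data hold 20679 spots and 19465 genes, of which 11 symbols occur under 2 identifiers. Total UMIs ranged from 17136670 (CAL-101 2) to 53992435 (control 3). For expression, UMIs were summed over the spots of each tumor, so that the mouse is the replicate, and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr by group, Benjamini-Hochberg adjustment at 0.05). TMM factors were 0.916, 0.978 and 0.861 in the control and 1.00, 1.27 and 1.02 in the CAL-101 tumors. The same test was run on the sums within each cluster with at least 20 spots in at least 2 tumors of each group, which 4 of 18 clusters met, and on the sums over T-cell-positive spots. A spot was T-cell-positive with at least 1 UMI of Cd3d, Cd3e, Cd3g, Cd8a or Cd8b1. Where one existed, a negative spot of the same tumor and cluster with a total within 10% was matched to it, and positive spots without a match were left out. This kept 689 of 777, 404 of 411 and 719 of 742 positive spots in the control tumors and 710 of 723, 704 of 708 and 1438 of 1461 in the CAL-101 tumors. The 2 sums per tumor were compared with tumor as a block, the 5 defining genes left out. Differences between a cluster and the other tested clusters were tested as a treatment-by-region term with tumor as block. Values are log2 differences with standard errors and TMM-scaled CPM with SD over tumors.

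Gene lists of cell types, signalling and metabolism were tested with camera in limma 3.58.1 on log CPM (prior count 2, preset correlation 0.01), again with the correlation estimated for each list, and with fry, whose counts are those of its directional form unless the mixed form is named. Shares of spots were compared by exact two-sided permutation of the 6 tumors, for which 0.1 is the smallest possible p. Shares with a T cell transcript were computed in spots thinned to 2000 UMIs, beside the share with a transcript of 5 B cell genes as background. Olfactory and vomeronasal receptor genes served as a further reading of background. Spots with at least 1% of their UMIs in keratinocyte and skeletal muscle genes were called skin and muscle spots.

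The tests, lists, comparisons and the genes to be named were fixed before the data were examined. Named are the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between groups, filled up by smallest p where fewer passed; 5 and 5 in each region and in T-cell-positive spots; the leading members of each list; and 12 fixed genes whatever their result. Some genes chosen by these rules are not reported here. Alternatives covered DESeq2 1.42.0, limma-voom, other scaling factors, low-count filters, spot filters, thinning of each tumor to the smallest tumor total, the replicate number as a block and each tumor left out. Added after the data were seen were voom with sample quality weights, cyclic loess, leaving out control 2 with CAL-101 2, cluster 16 or the spots without a group, and combinations of these.

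The procedure was tested on simulated data with up to 100 genes changed 2-fold and up to 100 changed 4-fold. The whole-tumor test recovered 59% and 97%, with 15 false calls among 171. T-cell-positive spots between groups gave 58% and 92% (7 false of 157), and matched spots 100% and 100% (14 of 214). Cluster 1 gave 63.9% and 96.8% (3 of 156), cluster 7 53.1% and 95.9% (21 of 166, the largest share of false calls), cluster 14 29.7% and 78.9% (6 of 108), and cluster 15 44.8% and 97.7% (6 of 135). The interaction of cluster 14 recovered 4.04% and 28.3% (0 of 32), and those of clusters 1 and 7 had 6 false calls of 138 and 8 of 130. Gene positions are RefSeq coordinates of GRCm38.p6. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.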

Results

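Spatial transcriptomes were measured in 6 B16-F10 melanomas, a pigmented mouse tumor line grown in the skin of Rag1-deficient mice, which lack mature T and B cells of their own. Each mouse received CD8 T cells of the Pmel line, whose receptor recognises the melanocyte protein encoded by Pmel. The cells had been kept in culture with CAL-101 (idelalisib, an inhibitor of the delta isoform of PI3 kinase) or with vehicle, and 3 tumors fell into each group. The series title gives the question: whether that exposure of the T cells alters their differentiation in the mouse and the metabolism, immune composition and inflammation of the tumor. One section per tumor was assayed on a slide of barcoded spots with probes for 19465 genes. The control tumors 1, 2 and 3 had 2907, 3930 and 4373 spots with 48229479, 48445908 and 53992435 unique molecular identifiers (UMIs). The CAL-101 tumors 1, 2 and 3 had 2606, 2634 and 4229 spots with 41625700, 17136670 and 47164917 UMIs. The median spot held 17149, 14246.5 and 12165 UMIs in the control tumors and 15320.5, 5215.5 and 10656 in the CAL-101 tumors, so CAL-101 2 was the shallowest section.

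Over whole tumors, no gene passed the test; those named here had the smallest p among genes averaging at least 5 CPM without overlap between the tumors of the 2 groups. Ccn2, a matricellular protein gene on chromosome 10 from 24595442 to 24598683, averaged 132 ± 13.1 CPM (counts scaled to a common library size; SD, n = 3) in control and 46.7 ± 11.7 in CAL-101 tumors (log2 -1.50 ± 0.19, SE). Tnc, the gene of the matrix protein tenascin C, had 48.4 ± 11.1 against 19.4 ± 3.57 CPM (log2 -1.32 ± 0.21). The transcription factor gene Egr1 had 35.0 ± 6.94 against 14.4 ± 2.26 CPM (log2 -1.28 ± 0.19). The other genes with the smallest p on that side were the sphingosine kinase gene Sphk1 (-1.40), the kinase gene Sgk1 (-1.01), Tmem252 (-1.07) and Wfdc13 (-0.93). They also included the adenylosuccinate synthase gene Adssl1 (-0.85) and Thbs4, a thrombospondin gene that averaged 11.1 ± 9.98 against 0.331 ± 0.0717 CPM (-5.10). On the opposite side stood Rdm1 (0.91 ± 0.18), the exocytosis gene Sytl2 (0.95 ± 0.19), Hsd17b1 (0.99), Gnb3 (0.92) and Wdr78 (0.92). With them stood Sema6d (0.85), Pdzk1ip1 (0.67), Cntfr, a receptor for ciliary neurotrophic factor (0.63), Ypel2 (0.61) and Morn2 (0.49). In edgeR's quasi-likelihood test 0 of 19154 genes passed an adjusted p of 0.05 and the smallest adjusted p was 0.197, while 4787 genes had an unadjusted p under 0.05. DESeq2 called 132 genes, 125 of them lower in CAL-101, limma-voom called 0, and limma-voom with quality weights per sample called 8184. Those weights were 3.61, 0.978 and 1.07 in the control tumors and 0.598, 0.115 and 3.87 in the CAL-101 tumors. That count therefore leans mainly on control 1 and CAL-101 3. Without CAL-101 2 the edgeR test called 58.

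**Figure D1:**
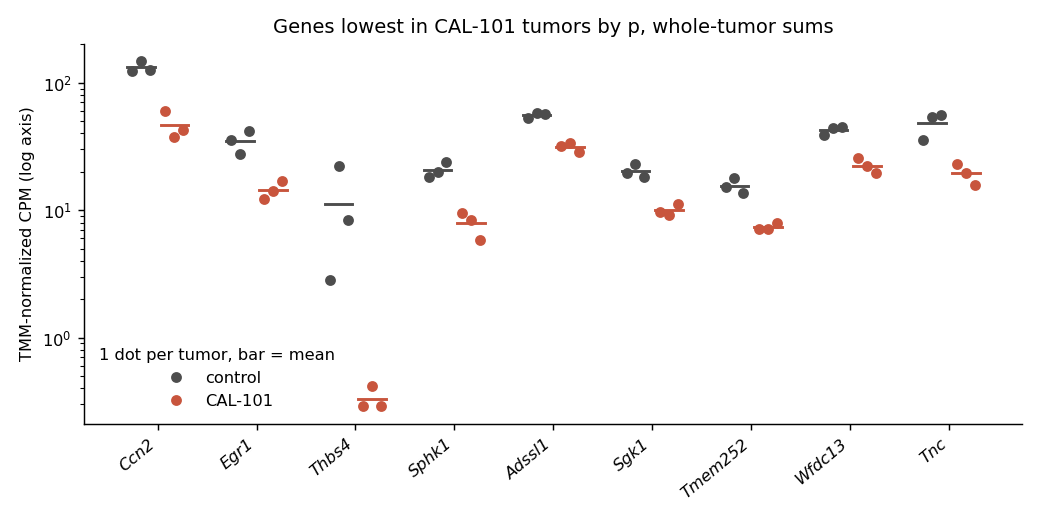
TMM-normalized CPM of 9 of the 10 genes lowest in the CAL-101 tumors by p, on a log axis, with 1 dot per tumor and a bar at the mean of each group of 3. The CAL-101 dots lie below the control dots for each of these genes, with Ccn2 at a mean of 46.7 against 132 CPM.

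The 5-tumor comparison without CAL-101 2, a planned run singled out for naming genes only after the data were seen, held 53 lower and 5 higher genes. Contractile genes of skeletal muscle had its largest differences: Acta1, skeletal alpha-actin, averaged 183 ± 189 CPM in control and 0.205 ± 0.0662 in the other CAL-101 tumors (n = 3 and 2; log2 -9.81 ± 1.20, edgeR adjusted p 0.0159). Mybph, Tnnt3, Atp2a1, Myh4, Casq1, Tnnc2 and Tcap were among the 10 lowest with it, as was Thbs4 (-5.25). Mybph had no UMI in either remaining CAL-101 tumor. Skin and muscle signal lay mainly in 1 section: spots with at least 1% of their UMIs in keratinocyte and muscle genes made up 14.8% of control 2, 1.51% of control 1, 0.823% of control 3, 0.645% of CAL-101 2 and none of CAL-101 1 and 3. The 5 higher genes were Fxyd1 (0.97 ± 0.14), Zfp467 (0.84), the microtubule protein gene Mapt (0.83), the extracellular chaperone gene Clu (0.81 ± 0.11) and Cntfr (0.70). With the skin and muscle spots also left out, 80 genes passed.

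Genes of the transferred cells did not pass the test in whole tumors. Their levels were low: Cd8a had 2.50 ± 0.510 CPM in control and 4.53 ± 0.949 in CAL-101 tumors (log2 0.86 ± 0.29), Cd3e 6.42 ± 3.47 and 13.96 ± 4.11 (1.12 ± 0.40), and the checkpoint receptor gene Pdcd1 6.33 ± 3.45 and 12.0 ± 2.73 (0.93 ± 0.38). Differences were 0.90 ± 0.49 for Slamf6 and -0.01 ± 0.41 for Tcf7, both used as markers of progenitor exhausted cells, at levels near 1 CPM. Olfactory receptor genes, a reading of background, had a median of 0.746, 0.908 and 0.574 unscaled CPM in the control tumors and 0.985, 4.03 and 1.37 in the CAL-101 tumors. Their median log2 difference of 1.16 was no smaller than those of Cd8a, Cd3e and Pdcd1, but they lie at lower abundance. Over the 6 tumors Cd8a averaged 3.51, Cd3e 10.2 and Pdcd1 9.17 CPM. Among 10 equal bins of tested genes by mean CPM, the bin holding Cd8a had a median log2 difference of 0.19. The bin holding Cd3e and Pdcd1 had -0.07, so the receptor genes are not a like comparison for them. Thy1 differed by -0.54 ± 0.25, Ifng by 0.62 ± 0.33 and Gzmb by -0.42 ± 0.42. Pik3cd, the gene of the inhibited kinase subunit, had 20.04 ± 1.27 and 21.0 ± 0.917 CPM (0.07 ± 0.13), and Pmel, the target of the transferred cells, had 3519 ± 1142 and 3651 ± 855 CPM (0.05 ± 0.30). Cxcl9 differed by 0.03 ± 0.38. Rag1, which these mice lack as a functional gene, was read at 0.580 ± 0.111 CPM in control and 1.36 ± 0.675 in CAL-101 tumors from 21 to 55 UMIs per tumor; whether its probe covers the disrupted part is not given in the sources used here.

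Tested as lists fixed beforehand, 15 of 40 gene groups differed between the CAL-101 and control tumors with camera at a preset correlation of 0.01, and 13 of the 15 lay lower. None of the 15 held with the correlation estimated for each list (adjusted p = 0.847 with an estimated correlation for 14 of them, and 0.846 for the TGF-beta list). Of tested energy metabolism genes, 18 of 18 oxidative phosphorylation genes lay below 0 (median log2 -0.40, adjusted p 3.86e-06; -0.14 and 0.0430 after cyclic loess), with Uqcrfs1 at -0.50, Ndufv1 at -0.55 and Atp5a1 at -0.66. All 12 tricarboxylic acid cycle genes (-0.43; Pdha1 -0.55, Fh1 -0.50) and all 12 glycolysis genes tested (-0.30; Hk1 -0.47) also lay below 0; after cyclic loess these medians were -0.17 and -0.04, and glycolysis did not pass (adjusted p 0.524). The proliferation list had a median of -0.48 with 12 of 13 members below 0 (Tyms -0.75, Birc5 -0.75) and 7 of them lower when adjusted over the list alone. Cholesterol synthesis (-0.52; Insig1 -0.77), fatty acid synthesis and uptake (-0.51; Scd2 -0.69), fatty acid oxidation (-0.21) and the amino acid and integrated stress response (-0.41; Slc7a5 -0.70) were lower too. Among stroma, macrophage genes (-0.94; Cd68 -0.87, Cd163 -2.16, Mrc1 -1.82), fibroblast and matrix genes (-0.71; Dcn -1.62, Pdgfrb -0.72; 7 of 12 lower adjusted over the list alone), TGF-beta response genes (-0.53) and immediate early genes (-0.34; Fosb -0.83) were lower, and skeletal muscle genes had the largest shift (-3.97; all 10 lower adjusted over the list alone). T cell identity genes (14 of 15 above 0, median 0.71) and B and plasma cell genes (8 of 10, median 0.83) were higher, the latter in mice that should lack B cells. Over all genes tested, 0 members of any list passed, and with the correlation estimated 0 of the 40 lists did. The directional fry test called 0 lists, and its mixed form, which takes members in either direction, called the TGF-beta list (adjusted p 0.008065).

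Lists that did not pass included the progenitor exhausted or stem-like T cell genes (median log2 0.58; Klf2 -0.71, Cxcr5 1.20), exhaustion and checkpoint genes (0.60; Cxcr6 1.26, Tox 1.37, both passing when adjusted over the list alone), cytotoxic effector genes (0.00) and NK cell genes (0.24). Interferon gamma response genes lay above 0 in 14 of 15 cases (0.20; Igtp 0.63) and type I interferon response genes in 10 of 11 (0.31; Ifi44 0.77). MHC class I (-0.10), MHC class II (-0.27), melanocyte and melanoma (0.05), endothelial (-0.05), hypoxia response (-0.12) and PI3K-AKT-mTOR component genes (-0.14) had smaller medians. With the trend with abundance removed by cyclic loess, chosen after the data were seen, 18 lists passed camera at the preset correlation, 10 of them among the 15 and in the same direction. The 8 others were type I interferon response (median 0.65), interferon gamma response (0.47), melanocyte and melanoma (0.36) and MHC class I genes (from -0.10 to 0.18), and neutrophil (from 0.79 to -0.22), mast cell (-0.72), alternative macrophage activation (-1.04) and inflammatory cytokine and NF-kB genes (-0.20). Glycolysis, B and plasma cell (-0.06), fatty acid oxidation (0.05), fatty acid synthesis and uptake (-0.31) and immediate early genes (-0.13) no longer passed. The estimated correlation was not used after loess. Alternative macrophage activation genes had a median of -0.67, and Arg1 in it had -1.71 ± 0.30. The remaining medians were -0.05 for monocyte, 0.79 for neutrophil, 0.30 for dendritic cell, and -0.18 for mast cell genes. They were -0.23 for smooth muscle and pericyte, 0.67 for keratinocyte, -0.70 for adipocyte, and 0.49 for erythroid genes, and -0.02 for inflammatory cytokine and NF-kB, -0.15 for complement, -0.07 for p53 and apoptosis and -0.01 for heat shock genes.

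The size of the difference between groups varied with abundance, and the gene lists sit at different abundances. The median log2 difference was 0.99 in the lowest of 10 equal bins of genes by mean CPM and -0.30 in the highest. Olfactory receptor genes, which the tumor has no known use for, were higher in CAL-101 for 965 of 965 tested, with a median of 1.16, which was 1.03 with DESeq2's size factors, 1.501 with upper-quartile factors, 0.54 without CAL-101 2 and 0.09 after cyclic loess, so its sign held under each scaling. Vomeronasal receptor genes were higher for 202 of 203, with a median of 1.28. The median over all tested genes was 0.08 with the main scaling, -0.02 with DESeq2's size factors and 0.35 with upper-quartile factors. Olfactory receptor UMIs per spot were 12.3, 11.2 and 7.34 in the control tumors and 15.9, 26.5 and 15.3 in the CAL-101 tumors (10.3 ± 2.61 against 19.3 ± 6.31, n = 3; two-sided exact permutation p 0.1, the smallest that 3 against 3 can give).

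**Figure D2:**
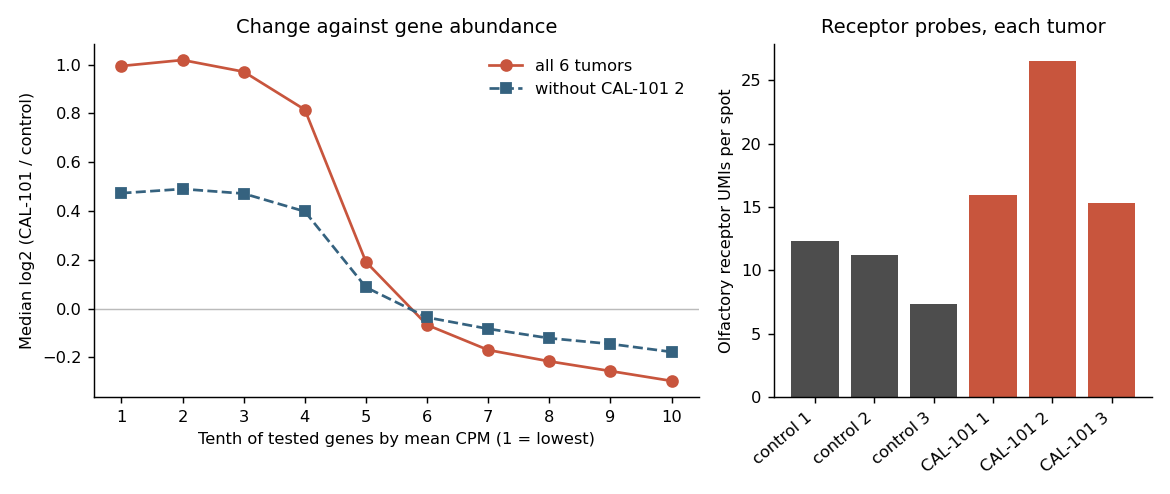
Left, the median log2 ratio of CAL-101 to control in each of 10 equal bins of tested genes by mean CPM, for all 6 tumors and without CAL-101 2; right, bars from 0 of olfactory receptor UMIs per spot in each tumor. The line runs from 0.99 in the lowest bin to -0.30 in the highest, and from 0.47 to -0.18 without CAL-101 2.

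The authors' clusters of spots were compared as shares of each section. Regions led by cytolytic genes (cluster 0: Gzmg, Gzmf, Gzmc, Prf1), hypoxia genes (cluster 2: Vegfa, Ndrg1, Slc2a1), interferon and MHC class II genes with T cell receptor segments (cluster 6: Cxcl9, H2-Aa, Trbv14), and muscle genes (cluster 9: Myh4, Acta1) held smaller shares in each CAL-101 tumor than in each control tumor. So did regions led by stress-response genes (cluster 11: Fgf21, Trib3, Chac1) and matrix genes (cluster 16: Ccn2, Tnc, Fn1), though both lay mainly in control 2. That tumor held 469 of the 487 spots of cluster 11, where control 3 had 2 spots and CAL-101 1 had 1. It held 190 of the 223 spots of cluster 16, where control 1 had 2 spots and each CAL-101 tumor 0. Cluster 0 held 23.9 ± 10.5% of spots in control (SD, n = 3) and 0.152 ± 0.204% in CAL-101 tumors, cluster 2 held 23.1 ± 13.0% and 0.571 ± 0.968%, and cluster 6 held 11.1 ± 8.60% and 0.290 ± 0.387%. These 6 of 18 clusters had exact permutation p 0.1 and adjusted p 0.3, chance giving such a separation in 10% of cases, and none passed. Clusters followed single tumors: 12 of 18 had at least 90% of their spots in 1 group and 6 in 1 tumor, with 64.8% of CAL-101 2 in cluster 3 and 56.2% of CAL-101 3 in cluster 1. Similar genes also led cluster 5 (Vegfa, Slc2a1), cluster 1 (Ifit2, Cxcl9) and cluster 10 (Acta1, Mylpf). CAL-101 tumors held 87.3%, 93.3% and 99.6% of their spots. Muscle genes led cluster 13 too, and Vegfa was a leading gene of cluster 14, with 99.8% and 87.5% of spots in control tumors. Smaller shares of clusters 2, 6 and 9 are therefore no measure of less hypoxia, interferon or muscle signal. The clusters were built from expression, so a share and the levels of its leading genes are not separate observations.

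**Figure D3:**
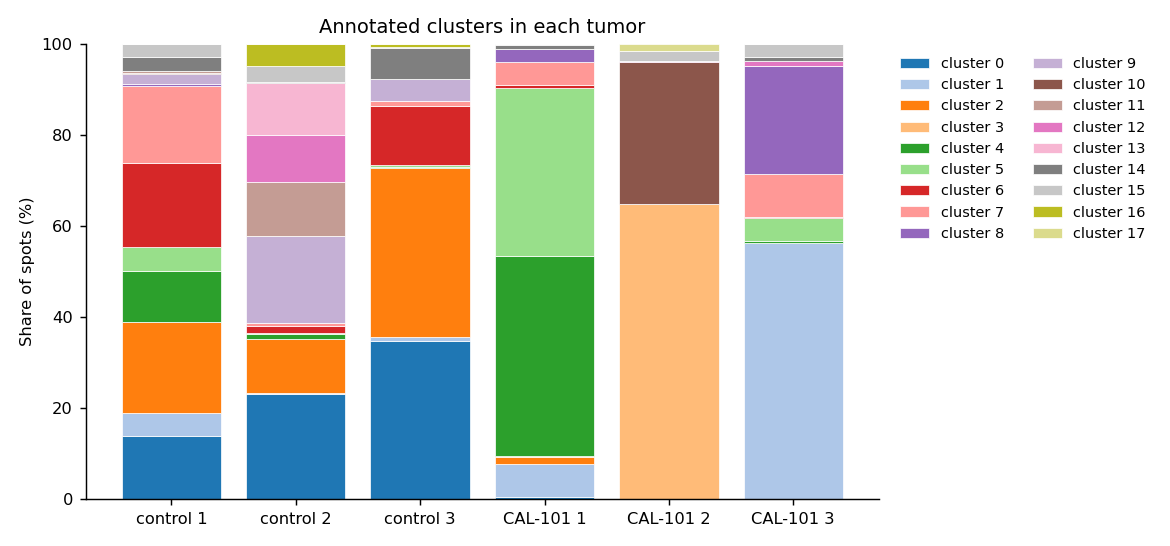
Share of the spots of each section in each of the 18 annotated clusters, in percent, 1 stacked bar per tumor. Cluster 0 takes 13.8%, 23.2% and 34.8% of the control sections and at most 0.384% of a CAL-101 section.

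In cluster 1, a region led by interferon-inducible genes (Ifit2, Cxcl9, Gbp2), 12 of 10360 genes passed (4 up, 8 down). The sums held 148 and 30 spots of control 1 and 3 against 188 and 2376 spots of CAL-101 1 and 3. Of all spots of this cluster 86.5% lay in CAL-101 3, so the comparison is very uneven. Gzmf fell from 187 ± 27.5 to 58.5 ± 12.6 CPM (SD, n = 2 tumors per group; log2 -1.69 ± 0.17, edgeR adjusted p 0.000281), Gzmg by 1.51 ± 0.20 on the log2 scale and Gzmb, a main cytolytic granule protease, by 1.16 ± 0.21. Gzmb, Gzmc, Gzmf and Gzmg lie in one array of related genes on chromosome 14, where Gzmf runs from 56205263 to 56211407, so signal shared between near-identical copies cannot be ruled out. Apod (-1.28), Egr1 (-1.40), Ccn2 (-1.001) and the MHC class II genes H2-Aa (-0.96) and H2-Eb1 (-0.91) fell as well. The complement gene C1qa (2.23 ± 0.35), the chemokine gene Ccl8 (2.02), the adipsin gene Cfd (3.68) and the collagen gene Col3a1 (1.14) rose. Of the lists, MHC class II genes (7 of 7 below 0, median -0.69), MHC class I genes (-0.29) and immediate early genes (-0.25) were lower and macrophage (1.25) and adipocyte genes (1.07) higher, with adjusted p = 0.865 with an estimated correlation for each of the 5. The cytotoxic effector list did not pass (6 of 8 below 0, median -0.57, adjusted p 0.05095; adjusted p = 0.865 with an estimated correlation). The count was 3 without control 1, 0 without control 3, 46 without CAL-101 1 and 40 without CAL-101 3, each leaving 1 tumor in a group that is assumed to vary like the others; it was 38 with no low-count filter and DESeq2 called 6.

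In cluster 7, a region led by collagen and resident macrophage genes (Sfrp2, Col3a1, F13a1, Mrc1), the scavenger receptor gene Marco fell from 124 ± 20.9 to 33.2 ± 5.37 CPM (n = 3 and 2; log2 -1.94 ± 0.23, edgeR adjusted p 0.0200) and was the single gene of 9913 to pass. Below the threshold, Arg1 had -2.40 ± 0.42, Cd163 -1.60 ± 0.296, Mmp12 -1.45 and Tnnt3 -5.26, while Prph had 1.81 ± 0.26, Hbb-bs 1.91, Hba-a2 1.597, Sfrp2 1.47 and the interferon-inducible Ifi44 1.15. Among the 16 lists past the camera test, type I interferon response genes (11 of 11 above 0, median 0.55), interferon gamma response (0.33), hypoxia response (0.26), heat shock (0.31) and erythroid genes (1.597) were higher. Macrophage (-0.51), alternative macrophage activation (-0.89), mast cell (-2.72), skeletal muscle (-3.41), adipocyte (-1.45), dendritic cell (-0.25), cytotoxic effector (-0.26), cholesterol synthesis (-0.38), fatty acid synthesis and uptake (-0.26), oxidative phosphorylation (-0.14) and tricarboxylic acid cycle genes (-0.15) were lower. None held in the second form of the test, with adjusted p = 0.536 with an estimated correlation as the smallest. The gene count was 11 without control 1, 2 without control 2, 0 without control 3, 16 without CAL-101 1 and 3 without CAL-101 3; it was 83 with no low-count filter and 7 with DESeq2.

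Cluster 14, a region of 440 spots at a median of 2867 UMIs led by Btbd35f2, Srgap1 and Vegfa, had 2 of 4132 genes past the threshold between 2 tumors per group. Summed were 85 and 292 spots of control 1 and 3 against 22 and 33 spots of CAL-101 1 and 3. The splicing factor gene Magoh rose from 11.1 ± 2.99 to 87.95 ± 2.38 CPM (log2 3.09 ± 0.56, edgeR adjusted p 0.0333). Its CAL-101 level rests on these few shallow spots. Fth1, the ferritin heavy chain gene, fell from 8514 ± 1778 to 3783 ± 1140 CPM (-1.16 ± 0.21, edgeR adjusted p 0.0285). H2-M3 (-2.58), S100a6 (-1.12), Sp140 (2.08) and Mki67 (1.24) did not pass. MHC class II genes were lower (6 of 6, median -0.84) and cholesterol synthesis genes higher (6 of 6, 0.99) as lists, both with adjusted p = 0.953 with an estimated correlation. Without CAL-101 1 the count was 0 and without CAL-101 3 it was 16; it was 48 with no low-count filter and DESeq2 called 23. Cluster 15, with a median of 96.5 UMIs per spot, had 0 of 274 genes past the edgeR threshold, 25 at an unadjusted p under 0.05 and 0 with DESeq2; Dct, a pigment enzyme gene, had 1.13 ± 0.41 and Ctsl -1.67 ± 0.51.

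In cluster 1 against the other tested clusters of the same tumors, Plvap, a gene of fenestrated endothelium, had an interaction of -2.37 ± 0.24 (edgeR adjusted p 9.04e-13), Ccl8 2.69 ± 0.40 and C1qa 2.44 ± 0.37, and 24 of 11372 genes passed (7 higher, 17 lower). In cluster 7, Cfd had -4.60 ± 0.61 (edgeR adjusted p 3.49e-06), the haptoglobin gene Hp -2.93 ± 0.42 and C1qa -2.08 ± 0.35. There 9 of 11295 genes passed (1 higher, 8 lower). Clusters 1 and 7 are each part of what the other is compared with, so their opposite signs for C1qa are not separate observations. In cluster 14, 4 of 10217 passed (1 higher, 3 lower), with H2-M3 at -2.83 ± 0.62 (edgeR adjusted p 0.0317). Without control 1 the counts were 57, 30 and 9. The count of cluster 7 was 0 without control 2 and 5 without CAL-101 3, and that of cluster 14 was 1 without control 3 and 0 without CAL-101 3.

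The share of spots with a UMI of Cd3d, Cd3e, Cd3g, Cd8a or Cd8b1 was, in spots thinned to 2000 UMIs, higher in each CAL-101 tumor than in each control tumor. So was the share with a UMI of B cell genes, which measures background in these mice. The T cell share was 3.49 ± 1.21% in control and 8.52 ± 3.27% in CAL-101 tumors (SD, n = 3; two-sided exact permutation p 0.1, the smallest possible). The B cell share was 3.998 ± 0.147% and 5.88 ± 0.939% (exact permutation p 0.1). Within tumors, the T cell share exceeded the B cell share by 0.943 percentage points in control 1, 0.0388 in CAL-101 1, 4.78 in CAL-101 2 and 3.11 in CAL-101 3, and lay below it in control 2 and 3 (-1.62 and -0.860). That difference between the shares was -0.511 ± 1.32 and 2.64 ± 2.41 points (exact permutation p 0.2). Unthinned, the T cell share was 18.1 ± 8.19% and 29.7 ± 4.1998%, and the B cell share 24.0 ± 2.62% and 24.0 ± 5.85%, with 18.9% in CAL-101 2 below each control tumor. In the other settings of the T cell share the groups overlapped: thinned to 5000 UMIs, CAL-101 1 had 11.4% against 11.5% in control 1 (exact permutation p 0.2), and with at least 2 UMIs in spots thinned to 2000, 0.233% against 0.435% (exact permutation p 0.2). Spots under 2000 UMIs were left out, 150, 838 and 72 in the control tumors and 27, 314 and 239 in the CAL-101 tumors. Exact binomial 95% intervals, which cover counting error only, reached from 1.884 to 2.995% in control 2 and from 10.4 to 13.1% in CAL-101 2.

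**Figure D4:**
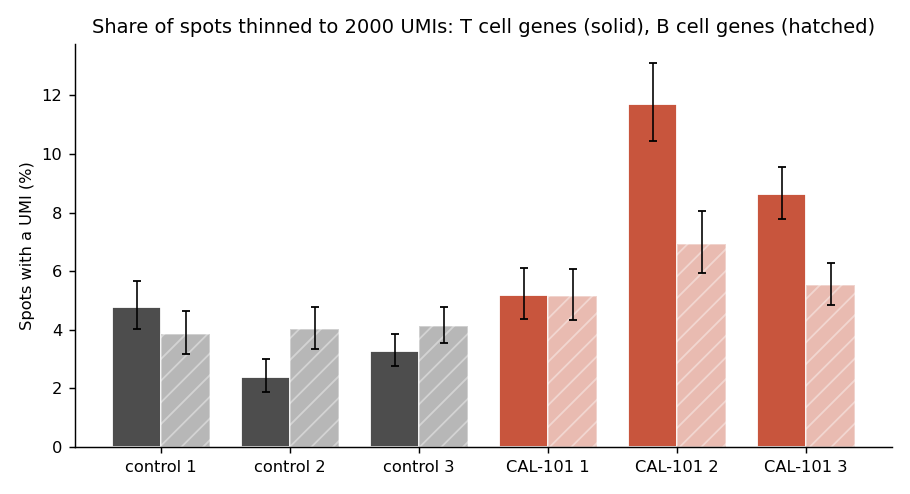
Share of spots, thinned to 2000 UMIs, with at least 1 UMI of T cell genes (solid bars) or B cell genes (hatched bars) in each tumor, with exact 95% binomial intervals. The T cell share stands at 11.7% in CAL-101 2 and 8.65% in CAL-101 3, and at 5.20% in CAL-101 1 beside a B cell share of similar size.

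In T-cell-positive spots taken alone, Tmem252 (20.7 ± 2.55 against 7.67 ± 0.871 CPM, n = 3; log2 -1.42 ± 0.17), Ccn2 (-1.54 ± 0.19), the proteoglycan gene Dcn (-1.69 ± 0.22) and Sphk1 (-1.51 ± 0.20) did not pass, with edgeR adjusted p from 0.0720 to 0.0746. Rdm1 (1.05), Sytl2 (0.93), Rgs11 (0.64), Zfp467 (0.82) and Cntfr (0.69) had the smallest p among higher genes averaging at least 5 CPM without overlap and did not pass either. In edgeR's test 1 of 17888 genes passed, a lower one. As lists, TGF-beta response genes (9 of 9 below 0, median -0.43), fibroblast and matrix (-0.85), macrophage (-1.19), alternative macrophage activation (-1.23), oxidative phosphorylation (-0.40), proliferation (-0.49) and skeletal muscle genes (-4.30) were among the 13 lower and 0 higher past the camera test. The smallest adjusted p = 0.485 with an estimated correlation belonged to the TGF-beta list, which was also the single one called by directional fry among them (adjusted p 0.00906). DESeq2 called 161 genes; the edgeR count was 38 without control 1, 129 without CAL-101 2, 5 in spots with at least 2 UMIs, and 0 without control 2, control 3, CAL-101 1 or CAL-101 3.

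In T-cell-positive spots, compared with spots of the same tumor and cluster matched for depth, 494 genes rose and 172 fell of 17431, and 345 and 117 of these went one way in all 6 tumors. Trbv14, the variable segment of the Pmel receptor beta chain, on chromosome 6 from 41135167 to 41135616, rose from 71.8 ± 36.9 to 149 ± 62.7 CPM (SD over 6 tumors; log2 1.06 ± 0.05, edgeR adjusted p 1.84e-18). Ms4a4b (1.06), the receptor constant genes Trbc2 (1.04) and Trac (0.81), the signalling adaptor gene Lat (0.86), the chemokine gene Xcl1 (0.81), Pdcd1 (0.80), Coro1a (0.75) and Ikzf1 (0.69) rose too, as did the connexin gene Gja4 of arterial endothelium (0.78). Among genes averaging at least 5 CPM that went one way in all 6 tumors, Col2a1 (-0.30), Mpp2 (-0.26), Selenbp1 (-0.25), Dnm1 (-0.23) and Espn (-0.23) fell most, and each of these 15 genes met that condition.

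With camera at the preset correlation 22 lists passed, 18 higher and 4 lower, and of these only the endothelial list held with camera's second form (adjusted p = 0.0361 with an estimated correlation). Directional fry called most of the 22, among them T cell identity, interferon gamma response and glycolysis (each fry adjusted p 0.00392), MHC class I (0.00905) and hypoxia response (0.0124). It did not call alternative macrophage activation (0.0523), type I interferon response (0.0579), melanocyte and melanoma (0.0657) or the amino acid and integrated stress response (0.103). The glycolysis list had adjusted p = 0.0880 with an estimated correlation, interferon gamma response adjusted p = 0.0991 with an estimated correlation, and hypoxia response and MHC class I and II adjusted p = 0.127 with an estimated correlation. Of single members, 14 of 15 interferon gamma response genes rose (Cxcl9 by 0.56 ± 0.03, Gbp2 by 0.24), as did 12 of 12 MHC class I (Tapbp 0.18, H2-T23 0.19) and 7 of 8 class II genes (H2-Ab1 0.32). Members that rose numbered 4 of 14 for exhaustion and checkpoint genes (Tox 0.88, Lag3 0.42), 8 of 13 for cytotoxic effector genes (Nkg7 0.60, Gzma 0.41), 3 of 13 for progenitor exhausted or stem-like genes (Id3 0.36) and 8 of 10 for T cell identity genes. Members also rose among those of monocytes (3 of 6; Plac8 0.43), macrophages (3 of 13; C1qa 0.34), complement (6 of 7; Serping1 0.42), fibroblasts and matrix (6 of 12; Col1a2 0.35), endothelium (8 of 12; Plvap 0.32) and, by smaller amounts, melanocytes (6 of 12; Mlana 0.10). Of hypoxia response genes 12 of 12 fell (Vegfa -0.19, Bnip3 -0.16, Car9 -0.14), and of glycolysis genes 8 of 12 (Slc2a1 -0.17). Adjusted over the list alone, the counts were 14, 12 and 8 for interferon gamma, MHC class I and class II, 12 for hypoxia and 10 for glycolysis. B and plasma cell genes had a median of 0.07, and none of 10 passed. Against all negative spots without matching, 1576 genes passed.

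**Figure D5:**
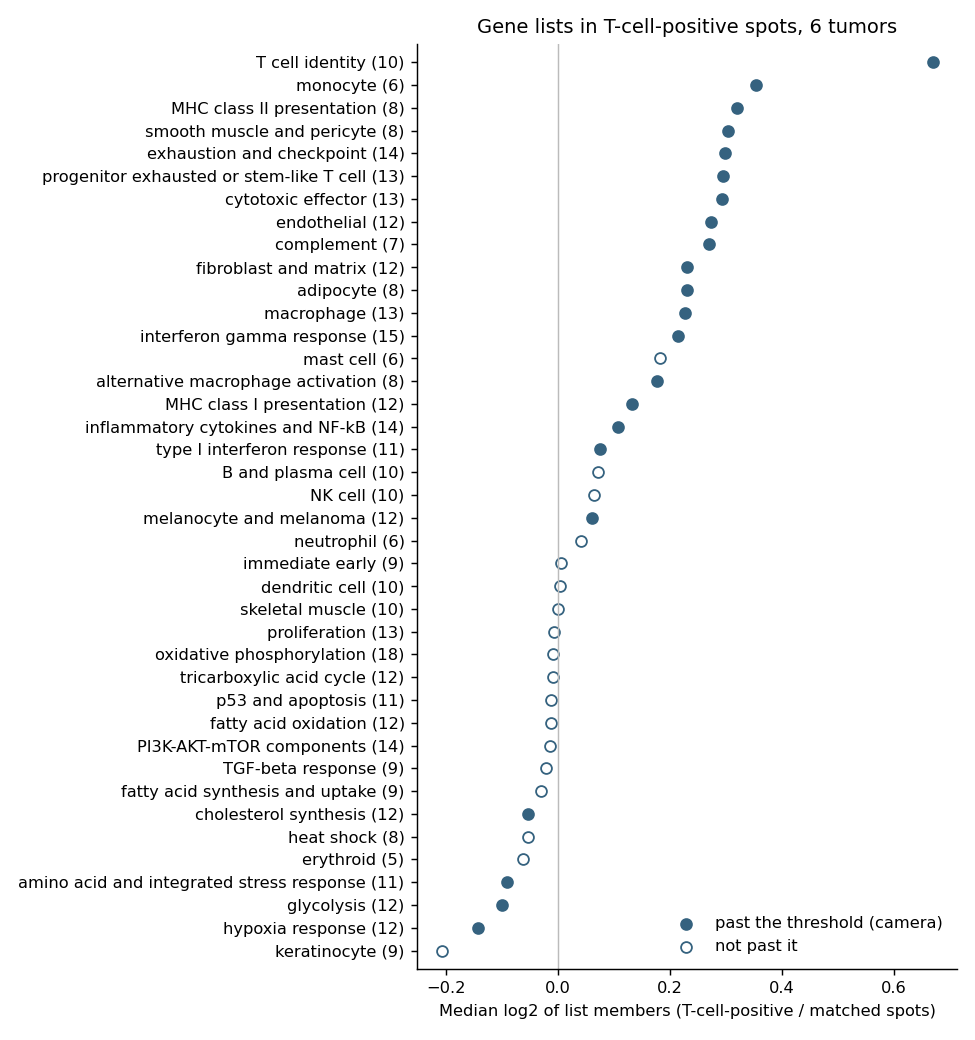
Median log2 ratio of T-cell-positive to matched spots over the measured members of each of the 40 gene lists (number of members in brackets), 6 tumors; filled points passed the camera test. T cell identity stands highest at 0.67, hypoxia response and glycolysis lie at -0.14 and -0.10.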

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

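Tests of the explanations below were chosen only after the result was seen; the interaction tests between regions were planned. Differences between groups of spots drew attention to the following genes. In cluster 1 against the other tested clusters, 24 genes had a different CAL-101 effect, among them the vessel genes Plvap (-2.37) and Gpihbp1 (-2.01), the macrophage genes Ccl8 (2.69) and C1qa (2.44) and the globin gene Hbb-bs (-2.22). In cluster 7 there were 9, with the adipocyte gene Cfd (-4.60), Hp (-2.93), C1qa (-2.08), Gpx3 (-1.65) and Hbb-bs (1.97). Clusters 1 and 7 each belong to the clusters that the other was compared with. Their opposite signs for C1qa and Hbb-bs are therefore not separate observations. In cluster 14 there were 4: Hba-a2 (-3.68), H2-M3 (-2.83), Pnrc1 (-1.75) and Hpgd (11.73), whose fitted value rests on near-zero counts. The difference between T-cell-positive and matched spots differed between CAL-101 and control tumors for 10 genes, among them Tmsb4x (0.36), Hba-a2 (1.04), Hbb-bs (1.05), Pf4 (0.71) and Krt14 (-2.02). That count was 3 without control 1, 18 without control 3, 4 without CAL-101 2 and 24 without CAL-101 3. For that last result 10 splits of the 6 tumors are too few for a share under 0.05; the real split gave 10 genes, the highest other gave 21, and 4 of the 10 splits gave as many.

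The first pattern is the trend with abundance: low-abundance genes lay higher and abundant genes lower in the CAL-101 tumors. More probe background in those sections may account for it, since olfactory receptor genes had a median log2 difference of 1.161. The lowest and highest of 10 equal bins of genes lay 1.291 apart with CAL-101 2 and 0.6508 without it, against 0.446 in the most extreme control tumor. With each tumor thinned to the smallest tumor total they lay 1.306 apart. Random thinning of the sums keeps the expected share of each gene, so it cannot decide whether the depth of CAL-101 2 is the cause. Against the mean of the control tumors, CAL-101 1 alone had 0.3793, CAL-101 2 alone 2.219 and CAL-101 3 alone 0.8598. The value of CAL-101 2 was the largest, and that of CAL-101 1 lay below the 0.446 of the most extreme control tumor. The depth and other traits of the section of CAL-101 2 stay open. Less tissue RNA over the same background cannot be told apart from more background, because the lowest CAL-101 value of 15.34 olfactory receptor UMIs per spot, against 12.3 in the highest control, also depends on how reads were shared. An effect of the treatment stays open: with the trend removed 10 of the 15 lists kept their direction and call, 5 did not and 8 others passed, among them MHC class I genes (median from -0.10 to 0.18) and neutrophil genes (from 0.79 to -0.22).

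The second pattern is a group of 9 of the 10 genes lower in the CAL-101 tumors with the smallest p, Ccn2 first. Their median log2 difference was -1.287 with skin and muscle spots left out, -1.279 without cluster 16 and -1.108 with the trend removed, against -1.284 with nothing removed. Removing the trend moved 17559 other genes by over 0.1, which argues against the trend as the whole cause. Leaving out skin and muscle spots moved all 10 skeletal muscle genes by over 0.1. Their median log2 difference was still -3.323, against -3.972 with nothing removed. Most of the muscle difference stayed, so that removal decides nothing and skin and muscle stay open. Leaving out cluster 16 moved 0 of its 7 other leading genes by over 0.1, so that test decides nothing and the region stays open. The 9 genes were picked by smallest p and none passed over whole tumors, so these tests do not show that the difference itself holds; an effect of the treatment stays open, as untested. For that count 10 splits are too few for a share under 0.05: the real split gave 0 genes and the highest other 1, and with a real count of 0 all 10 give as many by construction.

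The third pattern is the higher share of spots with a T cell transcript in the CAL-101 tumors. These spots do not hold background alone, as Trbv14 was higher in them by 1.062 than in matched spots. Whether background alone raises the share cannot be told apart from more T cells, because the excess over the B cell share differed with an exact permutation p of 0.2.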

How the results depend on the processing

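Tests with quality weights, cyclic loess, combined removals and the leave-one-out runs of lists in regions and of the T-cell-positive difference between groups were chosen only after the result was seen. Over 3314 settings of 267 single genes and lists, 2922 kept direction and side of the threshold, 121 lost the threshold, 241 gained it and 30 changed sign; the cause was not tested unless given. Whole tumor: 0 genes became 132 with DESeq2, 172 without control 2 and CAL-101 2, and 80 without CAL-101 2 and skin and muscle spots. The whole-tumor count was 8184 with quality weights, which were largest for control 1 and CAL-101 3, and 0 to 58 without 1 tumor. There 15 lists became 0 with an estimated correlation, 0 with directional fry and 13 to 18 without 1 tumor. Cluster 1: 12 genes became 38 with no low-count filter, 6 with DESeq2 and 0 to 46 without 1 tumor. Its 5 lists became 0 with an estimated correlation and 6 to 10; 24 interactions became 24 to 57. Cluster 7: 1 became 83, 7 and 0 to 16 likewise, 16 lists 0 and 9 to 18, 9 interactions 0 to 30. Cluster 14: 2 became 48, 23 and 0 to 16, 2 lists 0 and 1 to 5, 4 interactions 0 with DESeq2's size factors and 0 to 9. Cluster 15: 0 lists became 0 to 1. T-cell-positive spots: 1 became 161 with DESeq2, 5 with at least 2 UMIs and 0 to 129. Against matched spots 666 became 1576 with all negative spots and 497 to 679, and 10 differences between groups 3 to 24. Share with a T cell transcript: 3.43 to 6.70 points. Tcf7 changed sign with upper-quartile factors (0.234), voom (0.0337), thinning (0.166), quality weights (0.151) and without CAL-101 2 and skin (0.0622), and ranged from -0.126 to 0.221 without 1 tumor (0.0745 without CAL-101 2). With DESeq2's size factors and test, Pik3cd had -0.0259 and -0.0264, Pmel -0.0418 and -0.0430 and Cxcl9 -0.0625 and -0.0638. Without 1 tumor Pmel ranged from -0.176 to 0.287 (-0.123 without CAL-101 3), Cxcl9 from -0.537 to 0.316 (-0.197 without control 2) and Ccl5 in cluster 7 from -0.779 to 0.0715. Pmel had -0.0137 without control 2 and CAL-101 2, and Cxcl9 -0.0888 with voom. Loess gave Etfa 0.00963 and Acadvl 0.0302, and upper-quartile factors Acadvl 0.0260. Against all negative spots Cd163 had -0.162, Retnla -0.0827 and Insig1 0.000175. With loess the B and plasma cell list had adjusted p 0.897 and the fatty acid oxidation list 0.544. Replicate numbers do not pair the tumors: same-numbered deviations correlated at -0.0932, 0.285 and -0.00753, against 0.381, -0.172 and 0.283 for the best other number. With the number as a replicate block the counts were 98 (whole tumor), 43, 18 and 1 (clusters 1, 7 and 14) and 50 (T-cell-positive spots), with Tcf7 at 0.000241 and Cxcl9 at -0.0681.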

Other observations

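All tests of this part, the levels per tumor and the splits, were chosen only after the result was seen. Over whole tumors, granzyme genes of the chromosome 14 array had lower and T cell receptor genes higher means in the CAL-101 group, with overlap between the tumors of the 2 groups for Gzmf, Gzmg, Trbv14 and Trbc2. Gzmc averaged 226 ± 74.7 CPM in control and 92.6 ± 36.0 in CAL-101 tumors (n = 3; exact permutation p 0.1, the smallest possible), Gzme 18.9 ± 9.24 and 6.78 ± 2.92 (p 0.1, exact), Gzmf 247 ± 147 and 76.3 ± 55.1 and Gzmg 285 ± 173 and 117 ± 91.3 (both exact permutation p 0.2). Trbv14 averaged 60.3 ± 39.0 and 122 ± 42.3 CPM (exact permutation p 0.2) and Trbc2 90.03 ± 57.3 and 150 ± 49.2 (exact permutation p 0.3). Whether probes of these granzymes bind near-identical copies was not tested.

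Other splits of the tumors were counted beside the tests across genes. For T-cell-positive spots between groups, 10 splits are too few for a share under 0.05: the real split gave 1 gene, the highest other 1, and 2 of the 10 gave as many. For the gene lists the real split gave 15 and the highest other 21, with 9 of 10 as large, and 10 splits are too few for a share under 0.05. For T-cell-positive against matched spots, 1 of 32 sign swaps gave as many genes, the real one with 666. The highest other gave 346, with control 2 swapped. The spots were chosen by T cell transcripts in every tumor, which favours the real arrangement for genes expressed with them. The swaps therefore do not exclude chance for single genes.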
